A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

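Gene expression was measured by RNA sequencing in 10 libraries, 3 DMSO and 3 WM-1119 libraries of the human line MOLM-13 and 2 DMSO and 2 WM-1119 libraries of the mouse line ER-Hoxa9. Cells were treated for 4 days with 4 µM (MOLM-13) or 2 µM (ER-Hoxa9) WM-1119, RNA was extracted with RNeasy columns and libraries were made by a sequencing company, per the labels' protocols. The authors deposited 1 table per line with TPM per gene symbol, and each column sums to 1000000. The TPM were estimated by the authors with Salmon against hg38 and mm10, per the submitters' processing notes, and the assignment of hg38 to the human table and mm10 to the mouse table follows from the names of the builds. The Salmon version and the gene annotation are not given in the sources used here. Samples were grouped by line and treatment from the labels, each column was matched to its sample by treatment and number in its name, and 0 columns were left unassigned. The mouse columns carry a line name that the labels do not use, and were matched to ER-Hoxa9 as the mouse line of the series.

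TPM are relative to all other transcripts of a library, so an abundant transcript that rises lowers the values of all others. They keep no depth, so no counting interval or detection limit is given. The MOLM-13 tables held MIR6723 and MIR4461 at 12.8% to 21.7% of a library together, and the ER-Hoxa9 tables held Mir6236 at 7.23% to 10.7%. MIR6723 lies in the pseudogene MTCO1P12 (GRCh38 chromosome 1, 632325 to 632413), where 54 of its 65 stretches of 25 bases are identical to MT-CO1, and MIR4461 lies in MTND4LP30 (chromosome 5, 134928039 to 134928112), with 12 of 50 identical to MT-ND4L. No mitochondrially encoded gene symbol was listed, so the list of those genes has 0 members measured. An exact 0 was read only as listed at 0. Human coordinates are from GRCh38 with GENCODE release 29, and mouse coordinates were not used here.

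The tests, lists, rule for named genes and a first set of alternatives were chosen before the data were examined. Within each line, log2(TPM + 1) of genes with a mean of at least 1 TPM was fitted with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, and a two-sided Benjamini-Hochberg adjusted p under 0.05 was called. The 32 fixed gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a line with at least 3 tested members. The same lists were tested with an estimated correlation and with fry, which tests a list by itself. Calls of the lines were compared by symbol, ignoring case, with a one-sided Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

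The genes named for each line were the 10 with the largest change per direction among called genes whose WM-1119 libraries all lay on 1 side of all DMSO libraries, with a mean of at least 5 TPM in the higher group and no placeholder, microRNA or pseudogene symbol. Genes with the smallest unadjusted p completed the 10 where fewer passed. The rule also took 12 fixed genes and, where no member of a list passed, its most abundant member. The microRNA and pseudogene entries that were called lie outside that rule and were named after their values were seen, as were the other list members given as examples. Some genes that the rule takes are not reported here.

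Samples with the same replicate number deviated together from their group means in MOLM-13, with correlations across genes of 0.52, 0.44 and 0.61 for numbers 1, 2 and 3. All exceed 0.1, so the numbers were taken to pair the samples. This was decided before the calls of the fits were compared. The main fits had been fixed without a block, so in MOLM-13 they ignore this pairing, and their SEs include the spread between pairs. The labels do not say what the numbers share. Correlations of log2 values were 0.942 to 0.960 within MOLM-13 groups and 0.969 to 0.972 between same-numbered libraries, and 0 pairs of libraries held identical values.

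The fits were tested on simulated data with 200 changed genes, 50 per size. For MOLM-13 the data were drawn from the blocked fit, replicate differences included, so the block was bound to recover more there. The noise used variances shrunk by eBayes, so recovery in the real data may be lower. In MOLM-13, over 12219 genes, the fit without a block recovered 0%, 8%, 86% and 96% of log2 changes of 0.5, 1, 2 and 3, with 0 false calls, and the fit with the replicate block 44%, 96%, 100% and 98%, with 15 false calls. In ER-Hoxa9, over 11082 genes, the fit without a block recovered 2%, 80%, 98% and 100%, with 17 false calls. A list shifted by 0.5 was called at the preset correlation in both lines (adjusted p = 1.85e-41 and 3.29e-24, limma) with 0 other lists called. Noise was drawn for each gene on its own, so the simulation cannot show how often lists of genes that vary together are called falsely. With an estimated correlation the shifted list was missed, with an adjusted p of 0.287 and 0.226.

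Alternatives were a pseudocount of 0.1, no filter or a minimum of 5 TPM, median-of-ratios and quantile scaling, removal of ribosomal protein genes, eBayes without trend, a replicate block, an estimated correlation, fry, and leaving out each library in turn. Removal of the most abundant microRNA entries, small RNA genes not tested, the block combined with scaling, with that removal or without the replicate 3 pair, a threshold of 0.10, and overlaps at an unadjusted p under 0.05 were chosen after seeing the data. Levels were not compared between the lines, since each table was normalized separately.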

Results

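RNA was sequenced from 2 myeloid cell models to ask how inhibition of KAT6A alters their transcription. KAT6A is a histone acetyltransferase of the MYST family, and WM-1119 is a small molecule that blocks its enzymatic activity. MOLM-13 is a human acute myeloid leukaemia line that carries an MLL fusion gene. ER-Hoxa9 is a mouse myeloid progenitor line held by a HOXA9 protein under estrogen control, and it was grown with β-estradiol and stem cell factor. MOLM-13 cells received 4 µM WM-1119 and ER-Hoxa9 cells 2 µM, each for 4 days, and DMSO was the control. The 10 libraries comprised 3 DMSO and 3 WM-1119 libraries of MOLM-13, and 2 DMSO and 2 WM-1119 libraries of ER-Hoxa9. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Values were TPM, a share of each library scaled for transcript length, for 27800 human and 24493 mouse gene symbols. TPM keep no record of the number of reads, so the depth of each library is unknown. Between 12112 and 12416 genes reached 1 TPM in a MOLM-13 library, and between 11042 and 11446 in an ER-Hoxa9 library. Below, means carry an SD (n = 3 libraries per group in MOLM-13, n = 2 in ER-Hoxa9). Fold changes are log2 differences of TPM + 1, WM-1119 minus DMSO, with an SE from limma, and they understate the change of low genes. Examples of list members other than the most abundant one were chosen after their values were seen.

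In MOLM-13 cells, 4 fixed gene lists rose with WM-1119 relative to the other genes tested, and 6 fell. The lists that rose held markers of neutrophil maturation, markers of monocytes and macrophages, antigen presentation genes and lysosome genes. Those that fell held cytosolic ribosomal proteins, ribosome biogenesis genes, ATF4 and amino acid response genes, MLL-fusion and HOXA9 target genes, MYC targets and dendritic cell markers. Median shifts ran from -0.36 to 0.52 on the log2 scale, and no protein-coding gene passed on its own. The 28 lists were tested with limma's camera at a preset inter-gene correlation of 0.01. Other splits of the 6 libraries called 4 to 18 lists, so the number of calls does not set the treatment apart. None of the 10 calls held with an estimated correlation, where each had an adjusted p = 0.904. That setting also missed the simulated list shifted by 0.5 in both lines, with and without the replicate block. A call lost with it, here and below, is therefore shown neither to be false nor to hold. Only a shift of 0.5 was simulated, and fry was not run on the simulated data. With fry 0 lists were called in MOLM-13, with or without the replicate block (lowest adjusted p = 0.742 and 0.0763). KAT6A, the drug's target, stood at 18.3 ± 4.63 TPM in DMSO and 18.4 ± 3.95 TPM in WM-1119.

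Of 25 neutrophil maturation markers in the list, only 10 passed the filter on low values and were tested. All 10 had positive fold changes, with a median of 0.52 (camera adjusted p = 1.26e-06). S100A9, a calprotectin subunit, was at 13.4 ± 9.24 TPM in DMSO and 29.6 ± 16.3 TPM in WM-1119, and its partner S100A8 at 8.44 ± 4.43 and 15.4 ± 6.01 TPM. HP, haptoglobin, was at 4.81 ± 3.54 and 8.97 ± 6.76 TPM, and ITGB2, the beta-2 integrin chain, at 249 ± 52.1 and 306 ± 20.6 TPM. No member passed over all genes. Also 0 passed adjusted over the list alone, and 8 passed with the replicate block. Of the 20 monocyte and macrophage markers tested, from a list of 30, 17 had positive fold changes, with a median of 0.28 (camera adjusted p = 0.000343). LYZ, lysozyme, was at 1347 ± 689 TPM in DMSO and 2759 ± 612 TPM in WM-1119. CYBB, the catalytic subunit of the phagocyte NADPH oxidase (GRCh38 chromosome X, 37780011 to 37813461), was at 6.66 ± 2.04 and 16.4 ± 2.98 TPM, a fold change of 1.20 ± 0.24. TLR4, a receptor for bacterial lipopolysaccharide, was at 4.56 ± 1.31 and 8.34 ± 1.38 TPM, and ITGAM, the CD11b integrin chain, at 12.6 ± 5.23 and 16.1 ± 3.42 TPM. Adjusted over the list alone, 1 marker passed, CYBB (limma, adjusted p = 0.0282), and 7 passed with the replicate block. CD14 stayed below the expression filter, at 0.683 ± 0.636 TPM in DMSO and 1.01 ± 0.7301 TPM in WM-1119. Without DMSO replicate 1 the call for this list was lost (adjusted p = 0.128). In the blocked fit without the replicate 3 pair it was kept (camera adjusted p = 0.00100).

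Of 17 antigen presentation genes, 16 had positive fold changes, with a median of 0.34 (camera adjusted p = 8.83e-06). CD74, the invariant chain of MHC class II, was at 346 ± 45.8 TPM in DMSO and 615 ± 99.03 TPM in WM-1119, a fold change of 0.83 ± 0.19. B2M, the light chain of MHC class I, was at 962 ± 65.5 and 1277 ± 135 TPM, PSMB9, an immunoproteasome subunit, at 27.4 ± 7.26 and 42.03 ± 13.8 TPM, and HLA-C at 51.8 ± 13.1 and 70.9 ± 20.1 TPM; HLA-C shares sequence with other class I genes, so its level is uncertain. Of these, 0 passed adjusted over the list alone, against 10 with the replicate block. Of 25 lysosome genes, 24 had positive fold changes, with a median of 0.22 (camera adjusted p = 0.0006901). CTSZ, cathepsin Z, was at 139 ± 31.7 and 229 ± 36.6 TPM, and PSAP, prosaposin, at 197 ± 21.3 and 234 ± 5.62 TPM in DMSO and WM-1119. None passed adjusted over the list alone, against 3 with the replicate block.

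Among the lists that fell, 28 of 30 cytosolic ribosomal protein genes had negative fold changes, with a median of -0.15 (camera adjusted p = 4.30e-07). RPS18 was at 13416 ± 2903 TPM in DMSO and 11732 ± 967 TPM in WM-1119, RPL5 at 1956 ± 183 and 1657 ± 61.4 TPM and RPL14 at 1594 ± 71.4 and 1360 ± 28.8 TPM. Of 26 ribosome biogenesis genes, 23 were negative (median -0.09, camera adjusted p = 0.0108), among them NAT10, an RNA acetyltransferase, at 58.6 ± 10.9 and 48.2 ± 15.4 TPM. Of 20 ATF4 and amino acid response genes, 19 were negative (median -0.36, camera adjusted p = 3.69e-05). SLC7A5, a large neutral amino acid transporter, was at 136 ± 48.6 and 89.6 ± 19.1 TPM, DDIT4, an inhibitor of mTOR signalling, at 112 ± 89.98 and 66.1 ± 73.4 TPM, and ATF4 itself at 449.99 ± 140.1 and 396 ± 51.4 TPM. Of 7 dendritic cell markers tested, from a list of 17, 6 were negative (median -0.22, camera adjusted p = 0.0108). They included FLT3, a receptor tyrosine kinase, at 164 ± 15.1 and 142 ± 13.97 TPM, and SIGLEC6 at 7.35 ± 3.35 and 4.12 ± 2.197 TPM. In these 4 lists 0 members passed adjusted over the list alone, and with the replicate block 1 dendritic cell marker passed, SIGLEC6. Ribosomal protein genes took 39.9% and 34.0% of the TPM in the DMSO and WM-1119 libraries of replicate 3, and from 25.8% upwards in the other libraries. The ribosomal protein call was lost without DMSO replicate 3 (adjusted p = 0.469), and the ATF4 call without DMSO replicate 2 (0.0680), DMSO replicate 3 (0.469) or WM-1119 replicate 1 (0.627). The dendritic cell call was lost without DMSO replicate 2 (0.464), DMSO replicate 3 (0.0779) or WM-1119 replicate 1 (0.443). The ribosome biogenesis call was lost without WM-1119 replicate 2 (0.149) or 3 (0.338), and without DMSO replicate 1 its direction turned (0.944). Each of these fits breaks a pair. In the blocked fit without the replicate 3 pair, camera kept the ribosomal protein (0.00830), ATF4 (1.10e-06), dendritic cell (0.000754) and ribosome biogenesis (0.0131) calls. In the blocked fit of all libraries, these 4 lists had an adjusted p of 0.788 with an estimated correlation.

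Of 23 tested targets of HOXA9 and MLL fusions, 14 had negative and 9 positive fold changes, and the list fell relative to the other genes with a median of only -0.03 (camera adjusted p = 0.00971). Among them were SOX4, a transcription factor, at 17.7 ± 3.78 TPM in DMSO and 11.02 ± 2.298 TPM in WM-1119, BCL2, an inhibitor of apoptosis, at 52.1 ± 7.69 and 40.6 ± 5.76 TPM, and RUNX2, a Runt-domain transcription factor, at 21.7 ± 3.79 and 15.2 ± 1.87 TPM. By limma, 0 passed adjusted over the list alone, and 2 passed with the replicate block, SOX4 and BCL2. HOXA9 itself was at 74.9 ± 19.1 and 85.1 ± 26.3 TPM (fold change 0.17 ± 0.29), HOXA10 at 23.8 ± 7.57 and 29.5 ± 10.001 TPM, MEIS1, a HOXA9 cofactor, at 14.5 ± 2.28 and 16.3 ± 4.26 TPM, and MYB at 182 ± 37.6 and 185 ± 36.8 TPM. By same-numbered pairs, HOXA9 and HOXA10 were higher with WM-1119 in all 3, and MEIS1 and MYB in 2. With the replicate block HOXA9 and HOXA10 did not pass (limma adjusted p = 0.308 and 0.182). Of 26 MYC and MYC target genes, 16 were negative, with a median of -0.03 (camera adjusted p = 0.0207). MYC (chromosome 8, 127735434 to 127741434) was at 151 ± 21.8 TPM in DMSO and 109 ± 28.9 TPM in WM-1119, a fold change of -0.50 ± 0.25 that did not pass (limma adjusted p = 0.99999; 0.173 with the replicate block). It was lower in each WM-1119 library than in the DMSO library of the same number. NPM1, a nucleolar chaperone, was at 1451 ± 164 and 1226 ± 151 TPM, and ENO1, enolase, at 2201 ± 568 and 2167 ± 379 TPM. Of the MYC targets, 0 passed adjusted over the list alone, with or without the block. Without a filter on low values the calls ended, with an adjusted p of 0.0555 for the HOXA9 list and 0.0689 for the MYC list. Without DMSO replicate 1 or WM-1119 replicate 3, the HOXA9 list had an adjusted p of 0.114 and 0.105, and the MYC list of 0.678 and 0.357. In the blocked fit without the replicate 3 pair, camera kept the HOXA9 (0.00498) and MYC (0.0125) calls.

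**Figure D1:**
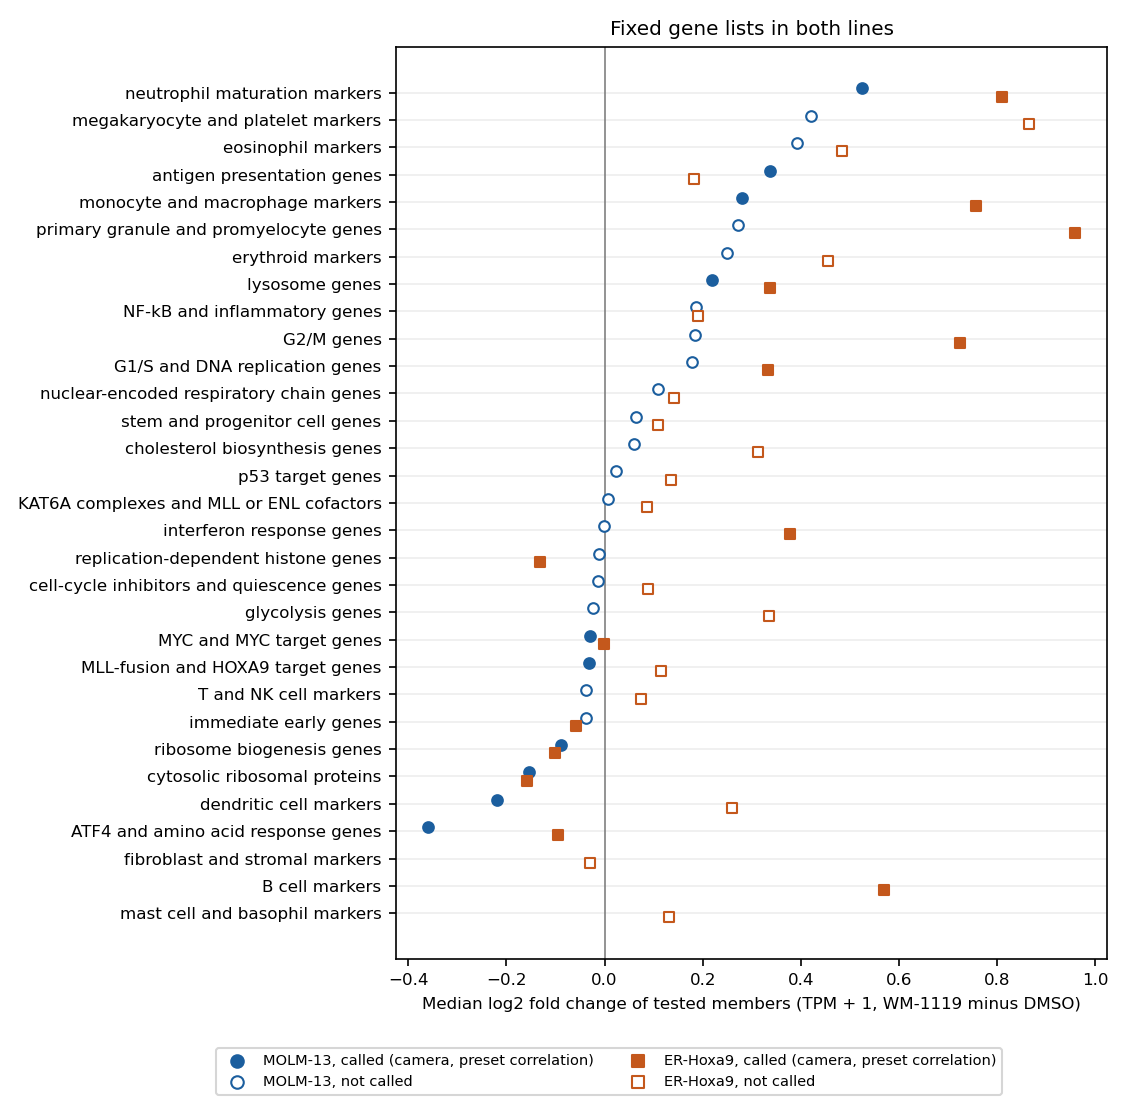
Median log2 fold change of the tested members of each fixed gene list (x axis, TPM + 1 scale), in MOLM-13 (circles) and ER-Hoxa9 (squares). Filled symbols were called by camera at the preset correlation, and no call held with an estimated correlation or with fry. The estimated correlation also missed a simulated list shifted by 0.5. Neutrophil maturation markers lie at 0.52 and 0.81, and ATF4 response genes at -0.36 and -0.09.

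Proliferation and other programmes were not called without the block. All 26 G2/M genes and 23 of 26 G1/S and DNA replication genes had positive fold changes (medians 0.18 and 0.18), with camera adjusted p of 0.199 and 0.503. With the replicate block both lists were called, at 0.000671 and 0.0356, as were the primary granule list (0.0742 without the block, 0.0138 with it) and the nuclear-encoded respiratory chain list (0.305 and 0.0281). With an estimated correlation in the blocked fit, these lists had an adjusted p of 0.788. In the blocked fit without the replicate 3 pair, only the primary granule list of these 4 was called (0.0409), and the G2/M list had an adjusted p of 0.0726, the G1/S list of 0.523 and the respiratory chain list of 0.144. With the block and the most abundant microRNA entries removed, the G1/S list had 0.0508 and the respiratory chain list 0.0543, and the latter had 0.163 with the block and median-of-ratios scaling. Without the block, the G2/M and G1/S lists were called below the other genes when DMSO replicate 3 was left out (0.0171 and 0.00892), and above them without DMSO replicate 1 (0.0231 and 0.00609) or WM-1119 replicate 3 (0.000202 and 0.00159). The G2/M list was also called without DMSO replicate 2 (0.00268), the respiratory chain list without DMSO replicate 1 (0.0115), and the primary granule list without DMSO replicate 1 (0.0173) or WM-1119 replicate 2 (0.0408). UBE2C, a mitotic ubiquitin-conjugating enzyme, was at 72.5 ± 18.6 TPM in DMSO and 93.5 ± 9.05 TPM in WM-1119, PCNA at 309 ± 153 and 353 ± 107 TPM, and PRTN3, proteinase 3 of the primary granules, at 5092 ± 2130 and 5598 ± 1527 TPM. The lists of KAT6A complexes, stem and progenitor genes, cell-cycle inhibitors, p53 targets, interferon response, NF-kB, immediate early, cholesterol, glycolysis and histone genes were not called, with adjusted p between 0.1097 and 0.944. The NF-kB list was called under median-of-ratios scaling (0.0239), with quantile normalization (0.0263) and with ribosomal protein genes removed (0.0288), and with no filter on low values the interferon list, at 0.0364. Each of these lists except that of stem and progenitor genes was called when at least 1 library was left out, with the lowest adjusted p from 7.71e-05 for NF-kB to 0.0429 for cell-cycle inhibitors. In the blocked fit without the replicate 3 pair, the cholesterol (0.0103), glycolysis (0.0165) and histone (0.0165) lists were called below the other genes. With an estimated correlation in the fit without the block, the lowest adjusted p of any list was 0.904. None of the members of these lists passed adjusted over the list alone; with the replicate block 5 primary granule genes, 6 NF-kB genes and the interferon gene BST2 did. BST2, an antiviral membrane protein, was at 209.8 ± 34.3 and 305 ± 53.002 TPM, and CDKN1A, the p21 cell-cycle inhibitor, at 205 ± 58.2 and 195 ± 40.4 TPM. Among markers of other lineages, erythroid, megakaryocyte, eosinophil and T or NK cell lists were not called (0.194 to 0.564), and 0 of their members passed adjusted over the list alone. With the replicate block 2 eosinophil markers passed adjusted over the list alone, RNASE2 and RNASE3 (limma adjusted p = 0.0265 each, fold changes of 0.58 and 0.66), as did the T cell markers CD3D (0.005404, fold change -1.05) and CD4 (0.0164, fold change 0.30). RNASE2 and RNASE3 are also among the 5 primary granule genes counted above. Without DMSO replicate 3 or WM-1119 replicate 1 the erythroid list was called (0.00477 and 0.0330), and without DMSO replicate 1 the eosinophil list (0.0355). Mast cell, B cell and stromal lists had fewer than 3 tested members, with fold changes of -0.06 for GATA2 and -0.66 for TPSB2 of the mast cell list and -0.06 for ACTA2 of the stromal list. TPSB2, a mast cell tryptase that shares sequence with another tryptase gene, passed adjusted over the list alone with the replicate block (limma adjusted p = 0.0377; 0.211 without it). The fetal globin HBG2, which shares sequence with HBG1, was at 25.003 ± 43.3 TPM in DMSO and 73.5 ± 127 TPM in WM-1119. Each of these means came from 1 library, with HBG2 at 0 to 75.0 TPM in DMSO and 0 to 221 TPM in WM-1119. RNASE2, the eosinophil-derived neurotoxin, was at 511 ± 197 and 740.02 ± 194 TPM.

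Gene by gene, limma called 0 genes higher and 1 lower at an adjusted p under 0.05 among 12436 tested. At an unadjusted p under 0.05, 259 were higher and 120 lower, against 622 by chance. This fit ignores the pairing by number, so its few genes do not show a lack of response. In the simulation this fit recovered 8% of log2 changes of 1, against 96% with the replicate block. The simulated data were drawn from the blocked fit, which favours the block by design. Those shares therefore do not give the recovery in the real data. With the replicate block 0 genes were called, and 1645 higher and 611 lower genes were under the unadjusted threshold. Median-of-ratios scaling of the blocked fit made that split 1104 to 1139. The called gene was MIR191, a microRNA gene (GRCh38 chromosome 3, 49020618 to 49020709, minus strand). It stood at 14.8, 22.5 and 12.5 TPM in the DMSO libraries and was listed at 0 in all 3 WM-1119 libraries (adjusted p = 0.00442; 0.0532 with the replicate block). Leaving out 1 library moved the counts. They were 1 higher and 4 lower without DMSO replicate 1, 1 and 5 without DMSO replicate 2, 0 and 3 without DMSO replicate 3 or WM-1119 replicate 1, 0 and 0 without WM-1119 replicate 2, and 1 and 1 without WM-1119 replicate 3. The other genes named here did not pass. Among genes higher in every WM-1119 library than in every DMSO library, the 10 with the smallest p were SLPI, PTAFR, GPR27, IL12RB1, GATM, LGALS2, IFI30, AOC1, ECI2 and GLIPR2. SLPI, a secreted leukocyte protease inhibitor (chromosome 20, 45252239 to 45254564), was at 1.1995 ± 0.396 TPM in DMSO and 12.3 ± 4.402 TPM in WM-1119 (adjusted p = 0.176; 0.112 with the replicate block). PTAFR, the platelet-activating factor receptor (chromosome 1, 28147166 to 28193936), was at 5.47 ± 1.16 and 14.3 ± 1.02 TPM, IL12RB1, an interleukin receptor chain, at 6.01 ± 0.412 and 12.3 ± 1.13 TPM, and IFI30, a lysosomal thiol reductase, at 44.03 ± 5.04 and 89.5 ± 11.1 TPM. GATM, an enzyme of creatine synthesis, was at 1.55 ± 0.525 and 6.2998 ± 1.68 TPM, and LGALS2, a galectin, at 2.36 ± 0.519 and 7.66 ± 2.08 TPM. Those lower in every WM-1119 library, by the same rule, included ENPP2, PTPN3, BAHCC1, WASF1, LRP5, SERF1B, E2F5, APP and BCL11A. ENPP2, autotaxin (chromosome 8, 119557086 to 119673453), was at 82.4 ± 7.98 TPM in DMSO and 32.8 ± 8.299 TPM in WM-1119, WASF1, an actin regulator, at 11.5 ± 3.05 and 4.34 ± 1.76 TPM, BAHCC1 at 9.97 ± 2.24 and 4.27 ± 1.002 TPM, and BCL11A, a repressor of fetal globin, at 10.5 ± 1.47 and 7.16 ± 0.398 TPM. SERF1B has a near-identical copy, SERF1A, so its value is uncertain.

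In ER-Hoxa9 cells, 8 fixed lists rose with WM-1119 relative to the other genes and 6 fell. The lists that rose in this relative sense held primary granule genes, neutrophil markers, monocyte and macrophage markers, lysosome genes, G2/M, G1/S and interferon response genes and B cell markers. Those that fell in it held cytosolic ribosomal proteins, ribosome biogenesis, ATF4 response, histone, MYC target and immediate early genes, and the MYC and immediate early lists had as many positive as negative fold changes. Median shifts ran from -0.16 to 0.96 on the log2 scale. Other splits of the libraries called 6 to 10 lists, and with only 3 splits in all chance cannot be excluded. Of the 31 lists tested with camera at the preset correlation, none of these 14 calls held with an estimated correlation, with an adjusted p = 0.798 for the G1/S list and 0.738 for each of the others. With fry 0 lists were called, with or without the replicate block (lowest adjusted p = 0.282 and 0.225). The median fold change of all tested genes was 0.12, which median-of-ratios scaling moved to -0.00, and camera tests a list against the other genes. Kat6a was at 15.4 ± 1.61 TPM in DMSO and 17.1 ± 0.653 TPM in WM-1119, and Hoxa9 at 262 ± 11.2 and 272 ± 15.7 TPM, a fold change of 0.06 that became -0.08 with that scaling. The level of Hoxa9 includes any transcript of the introduced gene that matches it.

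Of 15 primary granule and promyelocyte genes, 13 had positive fold changes, with a median of 0.96 (camera adjusted p = 0.006202). Clec11a, a stem cell growth factor, was at 16.1 ± 2.88 TPM in DMSO and 31.97 ± 2.45 TPM in WM-1119, Prss57, a granule serine protease, at 4.47 ± 1.61 and 11.4 ± 0.0769 TPM, and Fcnb, ficolin B, at 1.09 ± 0.589 and 4.62 ± 0.379 TPM. Ctsg, cathepsin G, was at 2529 ± 212 and 2875 ± 502 TPM. Of these genes 5 passed adjusted over the list alone. Of 13 neutrophil maturation markers tested, from a list of 27, 12 were positive (median 0.81, camera adjusted p = 0.00145). Hp, haptoglobin, was at 1.903 ± 1.51 TPM in DMSO and 10.1 ± 0.507 TPM in WM-1119, Itgb2 at 25.5 ± 0.754 and 56.1 ± 13.9 TPM, and Ltb4r1, a leukotriene receptor, at 12.5 ± 0.798 and 24.5 ± 7.93 TPM. Lcn2, lipocalin 2, was at 177 ± 55.6 and 176 ± 119.7 TPM. Here 6 passed adjusted over the list alone. Of 14 monocyte and macrophage markers tested, from a list of 31, 12 were positive (median 0.76, camera adjusted p = 0.0166). Among them were Itgam at 2.06 ± 1.05 and 7.68 ± 1.59 TPM, a fold change of 1.54 ± 0.30, Cd14 at 1.52 ± 0.598 and 4.603 ± 1.45 TPM, Cd68 at 3.897 ± 0.175 and 7.09 ± 0.463 TPM and Adgre1, the F4/80 antigen, at 3.31 ± 1.34 and 9.09 ± 2.84 TPM. These were the 4 that passed adjusted over the list alone. Ccr2, a monocyte chemokine receptor, was at 86.9 ± 21.3 and 79.9 ± 2.46 TPM. The monocyte call was lost without DMSO replicate 1 (adjusted p = 0.0712), with no filter on low values (0.172) and with a minimum mean of 5 TPM (0.278). All 24 tested lysosome genes were positive (median 0.34, camera adjusted p = 0.000113), among them Lipa, the acid lipase, at 8.51 ± 3.78 and 20.9 ± 0.229 TPM, Ctsb at 35.4 ± 4.55 and 52.9 ± 3.46 TPM and Psap at 208 ± 17.05 and 294 ± 20.5 TPM, and 0 passed adjusted over the list alone.

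All 26 G2/M genes were higher in both WM-1119 libraries than in both DMSO libraries (median 0.72, camera adjusted p = 1.09e-07). For a single gene, chance gives a separation either way in 33.3% of cases. Genes of this list may vary together, so the 26 separations are not independent and that share does not measure chance for the list. Plk1, a mitotic kinase, was at 40.2 ± 8.54 TPM in DMSO and 70.2 ± 10.7 TPM in WM-1119, Bub1b, a spindle checkpoint kinase, at 29.9 ± 8.64 and 51.4 ± 4.83 TPM, and Kif20a, a cytokinesis motor, at 27.2 ± 6.698 and 45.2 ± 5.41 TPM. All 26 G1/S and DNA replication genes were positive (median 0.33, camera adjusted p = 0.00669), with Pcna at 358 ± 45.4 and 451 ± 24.1 TPM, Fen1, a flap endonuclease, at 62.6 ± 7.06 and 101 ± 8.65 TPM, and Ccne2, cyclin E2, at 7.96 ± 1.57 and 12.1 ± 1.14 TPM. In neither list did a gene pass adjusted over the list alone. The G1/S call was lost without DMSO replicate 1 (adjusted p = 0.960) or WM-1119 replicate 2 (0.235). Of 17 interferon response genes, 16 were positive (median 0.38, camera adjusted p = 0.00145), with Oas1a at 5.47 ± 0.243 and 13.1 ± 1.85 TPM, Ifit2 at 2.39 ± 0.973 and 6.097 ± 0.198 TPM and Isg15 at 0.883 ± 0.345 and 2.76 ± 0.171 TPM, and these 3 passed adjusted over the list alone. With a minimum mean of 5 TPM the interferon call ended (adjusted p = 0.0795). All 7 B cell markers tested, from a list of 16, were positive (median 0.57, camera adjusted p = 0.0118). Among them were Vpreb3, a surrogate light chain component, at 9.46 ± 1.47 and 27.1 ± 3.23 TPM, and the B cell receptor chains Cd79a at 2.47 ± 1.58 and 9.92 ± 3.04 TPM and Cd79b at 23.5 ± 6.46 and 42.4 ± 2.24 TPM. These 3 passed adjusted over the list alone, and the list call was lost without WM-1119 replicate 2 (0.296).

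All 30 cytosolic ribosomal protein genes had negative fold changes in ER-Hoxa9 (median -0.16, camera adjusted p = 4.34e-12), with Rps18 at 7662 ± 627 TPM in DMSO and 6221 ± 259 TPM in WM-1119 and Rpl35 at 6273 ± 853 and 5034 ± 144 TPM. Ribosomal protein genes took 29.5% to 36.3% of the TPM of a library, and quantile normalization ended this call (adjusted p = 0.0963). Of 26 ribosome biogenesis genes, 21 were negative (median -0.10, camera adjusted p = 2.16e-06), among them Rrp9 at 65.3 ± 14.3 and 49.5 ± 0.204 TPM. Of 18 ATF4 response genes, 14 were negative (median -0.09, camera adjusted p = 5.56e-05), among them the amino acid transporter pair Slc3a2 at 244 ± 16.1 and 198 ± 7.13 TPM and Slc7a5 at 188 ± 13.3 and 153 ± 7.04 TPM, and Aldh1l2, a mitochondrial folate enzyme, at 16.1 ± 4.799 and 9.64 ± 2.64 TPM. Of 17 histone genes, 12 were negative (median -0.13, camera adjusted p = 0.000309), such as Hist1h3d at 27.8 ± 9.04 and 15.8 ± 6.41 TPM. The MYC list fell relative to the other genes although 13 of its 26 members were positive, with a median of -0.00 and a mean of 0.01 (camera adjusted p = 0.00669). Myc was at 309 ± 10.8 TPM in DMSO and 236 ± 16.2 TPM in WM-1119, a fold change of -0.39 ± 0.11 that did not pass (limma adjusted p = 0.313), and Npm1 at 2199 ± 18.8 and 1818 ± 159 TPM, while Tfrc, the transferrin receptor, was at 39.7 ± 2.62 and 49.9 ± 5.91 TPM. The immediate early list, with 8 of 16 negative, fell relative to the other genes at the deposited scale (camera adjusted p = 0.0133), with Dusp4 at 11.05 ± 1.799 and 7.83 ± 3.34 TPM, Ier2 at 78.1 ± 9.298 and 66.6 ± 1.02 TPM and Dusp5 at 14.6 ± 0.301 and 21.9 ± 1.73 TPM, but not under median-of-ratios scaling (adjusted p = 0.0861) or quantile normalization (0.0929). None of these 6 lists had a member that passed adjusted over the list alone. The histone call was lost without DMSO replicate 2 (adjusted p = 0.986) or WM-1119 replicate 1 (0.581), the immediate early call without DMSO replicate 2 (0.0626) or WM-1119 replicate 1 (0.581), and the MYC call without WM-1119 replicate 1 (0.0528).

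Targets of HOXA9 and MLL fusions were not called in ER-Hoxa9 (13 of 18 positive, median 0.11, camera adjusted p = 0.979). The test set this list below the other genes, against the sign of its median, which scaling also turned, to -0.01. Meis1 was at 48.5 ± 12.4 and 50.04 ± 7.09 TPM and Myb at 434 ± 10.1 and 407 ± 7.08 TPM in DMSO and WM-1119, and Hoxa10 was close to 0 TPM. Lists of stem and progenitor genes, KAT6A complexes, cell-cycle inhibitors, p53 targets and NF-kB genes had adjusted p of 0.304 to 0.843, and antigen presentation, cholesterol, respiratory chain and glycolysis genes of 0.0673 to 0.454. These last 4 were called above the other genes in some settings, and at the deposited scale had an adjusted p = 0.738 with an estimated correlation, or 0.958 for glycolysis. With the replicate block camera called all 4, at 0.0131, 0.0162, 0.0267 and 1.08e-05 in the order given. With an estimated correlation in that fit they had 0.825, or 0.841 for the respiratory chain. Antigen presentation was called with no filter on low values (0.0378), quantile normalization (0.0137), the most abundant microRNA entry removed (0.0397), or without DMSO replicate 1 (0.000239) or WM-1119 replicate 2 (0.0240). The cholesterol list was called with no filter (0.0445), quantile normalization (0.0364) or without WM-1119 replicate 1 (0.000704), and the respiratory chain list with no filter (0.00640) or the microRNA entry removed (0.0440). Glycolysis genes were called without DMSO replicate 2 (0.00646) or WM-1119 replicate 1 (0.000918), and below the other genes without WM-1119 replicate 2 (0.0400). Cd34, a progenitor surface marker, was at 754 ± 116 and 919 ± 34.6 TPM, Cdkn2a at 441 ± 0.507 and 382 ± 7.41 TPM, Psip1 at 57.9 ± 9.73 and 77.1 ± 4.76 TPM and Fdps, a mevalonate pathway enzyme, at 70.2 ± 25.3 and 122 ± 19.96 TPM. Markers of erythroid, megakaryocyte, mast, eosinophil, dendritic, T or NK and stromal cells were not called (0.245 to 0.990). Without DMSO replicate 2 the erythroid list was called (0.0180), and the eosinophil list was called below the other genes without WM-1119 replicate 1 (0.0362) and above them without WM-1119 replicate 2 (0.0238). Flt3 was at 153 ± 10.5 and 231 ± 17.03 TPM, Car2 at 30.1 ± 2.52 and 40.2 ± 3.597 TPM and Thbs1, thrombospondin, at 236 ± 31.4 and 444 ± 165 TPM. In limma 2 antigen presentation genes and 2 megakaryocyte markers passed adjusted over the list alone, and 1 marker each of the dendritic, mast and stromal lists. The dendritic marker was Flt3, also in the HOXA9 target list, and the mast cell marker Hdc, also in the primary granule list.

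**Figure D2:**
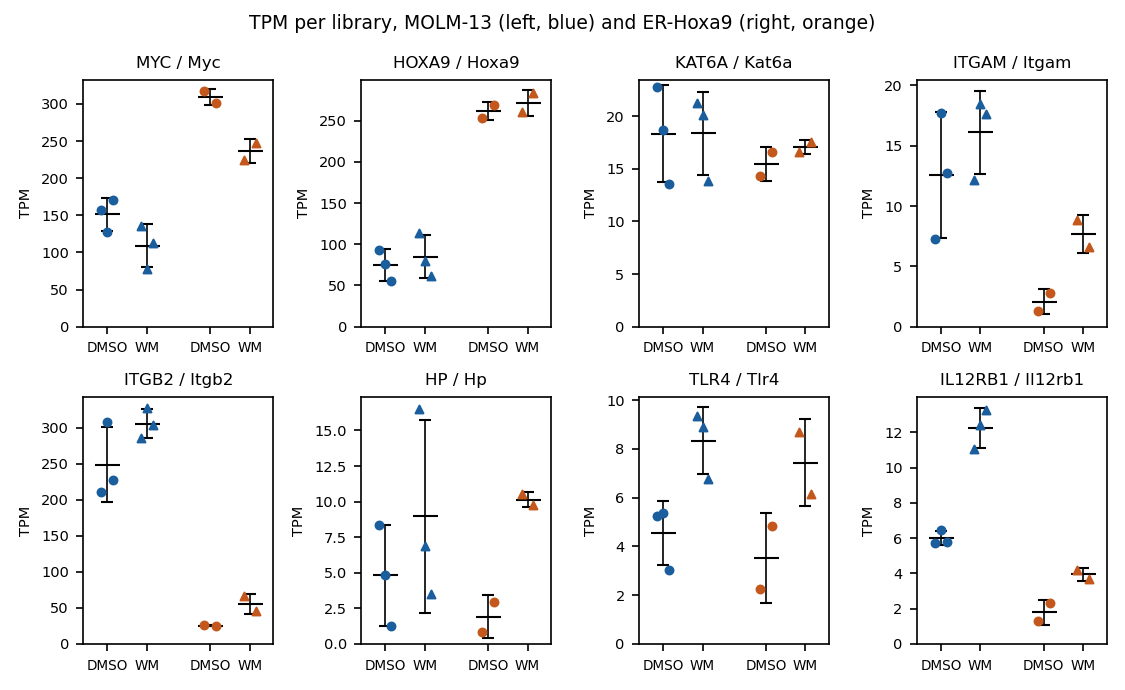
TPM of 8 genes in each library of MOLM-13 (blue) and ER-Hoxa9 (orange), with DMSO as circles and WM-1119 (WM) as triangles; horizontal bars are means and whiskers SDs (n = 3 and n = 2). None of these genes passed over all genes; MYC means were 151 and 109 TPM in MOLM-13, and KAT6A means were 18.3 and 18.4 TPM.

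Gene by gene, limma called 2 genes higher and 2 lower among 11362 tested, and all 4 were listed at 0 in 1 group. Apoo-ps, a pseudogene entry, was listed at 0 in both DMSO libraries and stood at 9.83 and 8.96 TPM with WM-1119 (adjusted p = 0.0298), and Mir1955 was listed at 0 and stood at 8.19 and 10.5 TPM (0.0406). Mir7050 stood at 14.8 and 13.6 TPM in DMSO (0.0288) and Mirlet7i at 10.9 and 13.97 TPM (0.0298), and both were listed at 0 with WM-1119. These calls were lost when any 1 library was left out, with 0 higher and 0 lower genes in each case. At an unadjusted p under 0.05, 1322 genes were higher and 128 lower, 91.2% higher, and median-of-ratios scaling made this 735 and 410, or 64.2% higher. Of the genes that did not pass, the 10 with the smallest p among those higher in both WM-1119 libraries than in both DMSO libraries were Rgs10, Ptms, Vpreb3, Col4a5, Casp1, Tmem176b, Inhbb, Speg, Akr1c13 and Lhpp. Rgs10, a regulator of G-protein signalling, was at 2.55 ± 0.341 TPM in DMSO and 20.9 ± 4.14 TPM in WM-1119 (adjusted p = 0.0543), Casp1, the inflammasome protease, at 10.1 ± 0.054996 and 24.2 ± 3.02 TPM, and Ptms, parathymosin, at 3.88 ± 0.397 and 13.8 ± 2.401 TPM. Those lower in both included Snhg1, Srpk1, Snhg15, Snhg5, Fam102b, Ciart, Zfas1, Dmwd and Snhg6. Snhg1, a host transcript of small nucleolar RNAs, was at 2240 ± 16.9 TPM in DMSO and 1149 ± 81.8 TPM in WM-1119, Zfas1, another such host, at 673 ± 157 and 341 ± 44.04 TPM, and Srpk1, a splicing-factor kinase, at 129 ± 13.2 and 77.5 ± 4.32 TPM.

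Relative to the other genes, neutrophil, monocyte and lysosome lists rose in both lines, and ribosomal protein, ribosome biogenesis, ATF4 and MYC lists fell in both. The MYC list in ER-Hoxa9 fell only in that relative sense, with a mean fold change of 0.01. These were the 7 lists called in both without the replicate block, of 28 tested in both. None of these calls held with fry, nor with an estimated correlation (adjusted p = 0.904 for each in MOLM-13 and 0.738 for each in ER-Hoxa9). Other splits of the libraries called up to 18 lists in MOLM-13 and 10 in ER-Hoxa9. How many lists such splits share between the lines was not tested. By limma 0 genes were called in both lines. In limma at an unadjusted p under 0.05 in both lines, 36 genes were higher in both against 13.8 for independent lists (one-sided Fisher's exact test, p = 3.07e-08), and 1 was lower in both against 0.272 (p = 0.239), among 8726 genes matched by symbol. With the replicate block in MOLM-13, 315 were higher against 139 and 7 lower against 3.09. With median-of-ratios scaling as well, they were 129 against 44.6 and 75 against 28.2. Fisher's test counts genes as independent and does not take in the spread between libraries, so its p cannot exclude chance. The following were chosen after the values were seen, since no gene was called in both, and their fold changes are given for MOLM-13, then ER-Hoxa9. GAPT, a myeloid adaptor protein, was at 0.98 ± 0.20 and 1.80 ± 0.38, CFP, properdin of the complement system, at 0.88 ± 0.21 and 1.28 ± 0.35, FCGRT, the neonatal Fc receptor, at 0.80 ± 0.17 and 1.61 ± 0.22, F13A1, a coagulation factor chain, at 0.78 ± 0.48 and 1.76 ± 0.66, and ANXA1, annexin A1, at 1.03 ± 0.40 and 0.81 ± 0.23. MYC was at -0.50 ± 0.25 and -0.39 ± 0.11, LONP1, a mitochondrial protease, at -0.35 ± 0.17 and -0.32 ± 0.11, and SLC7A5 at -0.54 ± 0.32 and -0.30 ± 0.11. Without the block, dendritic cell markers, antigen presentation genes and HOXA9 targets were called in MOLM-13 and not in ER-Hoxa9, and cell-cycle, interferon, primary granule, histone and immediate early genes in ER-Hoxa9 and not in MOLM-13. With the replicate block the G2/M (0.000671), G1/S (0.0356) and primary granule (0.0138) lists were called in MOLM-13 too, in the same direction. Those blocked calls were lost with an estimated correlation (adjusted p = 0.788 for each), and without the replicate 3 pair the G2/M (0.0726) and G1/S (0.523) calls were lost as well. In ER-Hoxa9 the block added a camera call for antigen presentation genes (0.0131), in the direction of MOLM-13, which was lost with an estimated correlation (0.825). Doses, species and tables differed between the lines, and the difference between them was not tested. Across the matched genes, which are not independent replicates, fold changes had a Pearson r of 0.251 and a Spearman rho of 0.270, and 63.8% had the same sign, or 59.8% after each line's median was subtracted.

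**Figure D3:**
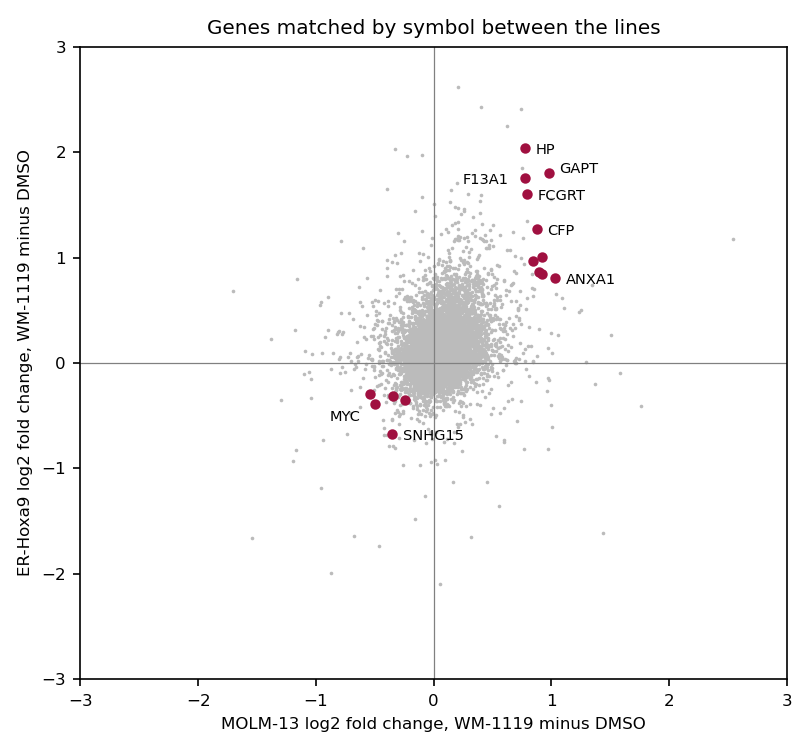
Log2 fold changes (WM-1119 minus DMSO) of 8726 genes matched by symbol, MOLM-13 on the x axis and ER-Hoxa9 on the y axis; each point is a gene, 2 genes lie outside the axes, and red points are 10 genes higher and 5 lower in both lines, chosen after the values were seen among genes with an unadjusted limma p under 0.05 in both (replicate block in MOLM-13). HP, at 0.78 and 2.04, and MYC, at -0.50 and -0.39, lie in opposite quadrants.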

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

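The rule behind this result looks for genes that moved in opposite ways in the lines in every library. Chance separates a single gene, either way, in 10% of cases in MOLM-13 and 33.3% in ER-Hoxa9. Some such genes are therefore expected by chance. LRP5, a Wnt co-receptor, was lower in each WM-1119 library than in each DMSO library of MOLM-13, at 12.7 ± 1.85 and 7.10 ± 1.44 TPM (SD, n = 3), a fold change of -0.77. In ER-Hoxa9 the mouse gene, Lrp5, was higher in both WM-1119 libraries, at 51.5 ± 1.93 and 63.6 ± 5.36 TPM (SD, n = 2), a fold change of 0.30. The median fold change of all genes tested in that line was 0.12. LRP5 passed in neither line, the difference between the lines was not tested, and no biological explanation was tested.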

How the results depend on the processing

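Tests of a 0.10 threshold, of unadjusted overlaps, of removed microRNA entries, of small RNA genes not tested and of the replicate block combined with another choice were chosen only after the results were seen. The causes of the changes below were not tested, except that fewer libraries or genes enter some fits. Depth is unknown, so its effect on low genes cannot be given. Where 1 ER-Hoxa9 library is left out, the lone sample is assumed to vary like the others. Of the named genes, 28 of 87 in MOLM-13 and 19 of 98 in ER-Hoxa9 changed sign in at least 1 setting. Over genes and settings, fold changes of named genes moved by less than their SE, without passing, in 1625 cases in MOLM-13 and 1207 in ER-Hoxa9, and by more in 16 and 154; SLPI passed in 1 setting and Rgs10 in 2.

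In MOLM-13, 0 genes higher became 8 with the replicate block at a threshold of 0.10, and 0 to 1 when 1 library was left out. The 1 gene lower became 0 with no filter on low values, with small RNA genes not tested, with the replicate block, and with the block plus median-of-ratios scaling or without the replicate 3 pair. It became 2 with no trend, at 0.10, and with the replicate block and the microRNA entries removed, 7 with the replicate block at 0.10, and 0 to 5 when 1 library was left out. Adjusted p of the HOXA9 target list was 0.0555 with no filter, 0.904 with an estimated correlation, 0.998 with fry and 0.000801 to 0.114 over left-out libraries. For the MYC list these were 0.0689, 0.904, 0.998 and 0.000675 to 0.678. Monocyte markers had 0.904 with an estimated correlation, 0.998 with fry and 6.92e-08 to 0.128 over left-out libraries, and neutrophil markers 0.904, 0.742 and 1.51e-06 to 0.000306. Other lists called, 6 in all, became 7 with no filter, median-of-ratios scaling or quantile normalization, 10 with the replicate block, which added primary granule, G1/S, G2/M and respiratory chain lists, 10 with the block without the replicate 3 pair, which added primary granule, cholesterol, glycolysis and histone lists, 9 with the block and median-of-ratios scaling, 8 with the block and the microRNA entries removed, 0 with an estimated correlation, 0 with fry and 6 to 16 over left-out libraries. Beyond the 4 lists it added and MIR191, the replicate block changed no other call of a list or of a gene over all genes.

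In ER-Hoxa9, 2 genes higher became 0 with a pseudocount of 0.1, no filter, a minimum of 5 TPM or the replicate block, 1 with median-of-ratios scaling, quantile normalization or the microRNA entries removed, 7 with no trend and 4 at 0.10. The 2 genes lower became 0 with a pseudocount of 0.1, no filter, a minimum of 5 TPM, the replicate block or small RNA genes not tested, and 9 with no trend. Both were 0 to 0 over left-out libraries. Adjusted p of the HOXA9 target list was 0.981 with no trend, 0.282 with fry and 0.388 to 0.976 over left-out libraries. MYC targets had 0.738 with an estimated correlation, 0.311 with fry and 0.0110 to 0.0528 over left-out libraries. Monocyte markers had 0.172 with no filter, 0.278 with a minimum of 5 TPM, 0.738, 0.311 and 0.00646 to 0.0712, and neutrophil markers 0.738, 0.282 and 3.05e-06 to 0.00570. Other lists called, 11 in all, became 14 with no filter, 13 with the microRNA entry removed, 15 with the replicate block, 10 with a minimum of 5 TPM, median-of-ratios scaling or ribosomal protein genes removed, 0 with an estimated correlation, 0 with fry and 11 to 12 over left-out libraries. Same-numbered ER-Hoxa9 libraries had a correlation of deviations of 0.21. That exceeds the 0.1 used for MOLM-13, but with only 2 pairs it cannot decide whether the numbers pair the samples. Splitting the libraries by number gave 570 genes at an unadjusted limma p under 0.05 and 10 called lists. The real split gave 1450 and 14, and the remaining split 88 and 6. With the replicate block 18 lists were called against 14, the added ones being antigen presentation (0.0131), cholesterol (0.0162), respiratory chain (0.0267) and glycolysis (1.08e-05). With an estimated correlation in that fit 0 lists were called, and these had an adjusted p of 0.825, or 0.841 for the respiratory chain.

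List directions turned in 56 cases in MOLM-13, over 17 lists, and 38 in ER-Hoxa9, over 13 lists. In 8 of these the list was called before or after, and they are given here with the range of adjusted p over left-out libraries. In MOLM-13 these were the G1/S list (0.00892, range 0.00159 to 0.994) and the G2/M list (0.0171, range 0.000202 to 0.729) without DMSO replicate 3, ribosome biogenesis without DMSO replicate 1 (0.944, the highest, from 1.94e-06), cholesterol without DMSO replicate 2 (0.000271, the lowest, up to 0.357), and glycolysis without DMSO replicate 2 (0.0310, range 0.00223 to 0.963). In ER-Hoxa9 they were immediate early genes with fry (0.998), glycolysis without WM-1119 replicate 2 (0.0400, range 0.000918 to 0.0715) and eosinophil markers without WM-1119 replicate 1 (0.0362, range 0.0238 to 0.960). Genes higher in both lines, 0 at the adjusted threshold and 0 to 0 over left-out libraries, were 36 at an unadjusted p under 0.05, 315 with the replicate block in MOLM-13, 36 with median-of-ratios scaling and 129 with both. Those lower in both, also 0, were 1, 7, 11 and 75.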

Other observations

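Of the tests in this part, those of small RNA stability, of the MIR191 host transcript and of transcript length were chosen only after the result was seen, as were the genes and the list of host transcripts described next. Several host transcripts of small nucleolar RNAs, noncoding RNAs whose introns hold those small RNAs, were among the genes of smallest p that were lower in ER-Hoxa9 with WM-1119. Of 15 such genes, 10 had negative fold changes, 7 were lower and 1 higher at an unadjusted limma p under 0.05, and the median was -0.40. The list was made because of Snhg1, Snhg15, Snhg5, Zfas1 and Snhg6, so these values are no test of it in ER-Hoxa9. Of the 10 others, 5 were negative and 5 positive, 2 lower and 1 higher at that threshold, with a median of -0.01. In MOLM-13, 15 of 23 were negative with a median of -0.11, and by limma 0 were lower at that threshold, against 4 with the replicate block. Gas5 was at 251.5 ± 82.4 TPM in DMSO and 173 ± 19.9 TPM in WM-1119 in ER-Hoxa9 (SD, n = 2). In MOLM-13, whose values did not prompt the list, the hosts had a camera p of 0.00978 at the preset correlation and 0.451 with an estimated one; no exact test applies to these lists.

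Single markers of other lineages passed adjusted over the list alone in ER-Hoxa9, though their lists were not called (camera adjusted p = 0.261 for megakaryocyte and 0.990 for stromal markers) and none passed over all genes. Transcripts of the platelet glycoprotein gene Gp9 were at 8.60 ± 4.14 and 27.3 ± 1.79 TPM in DMSO and WM-1119, of the integrin chain gene Itgb3 at 7.68 ± 3.18 and 20.6 ± 1.55 TPM, and of Thy1, of the stromal list, at 6.78 ± 2.83 and 19.7 ± 1.46 TPM (SD, n = 2). Adjusted over the list alone, Gp9 and Itgb3 both had a limma adjusted p of 0.0128, and Thy1 of 0.0107, while 3 of the 4 tested stromal markers had negative fold changes. Brpf1, a scaffold of KAT6A complexes, was at 18.9 ± 0.465 and 19.5 ± 0.717 TPM, and Kat6b, the paralog of Kat6a, at 4.90 ± 0.342 and 4.44 ± 0.134 TPM.

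Fold changes of the 2 lines went together across 8726 genes, with a Pearson r of 0.251. Of 30 combinations of a split of each line's libraries, 2 gave an absolute r as large, the real one included, and the highest other was 0.253, so by r chance cannot be excluded. By Spearman's rho, 0.270, only the real one of the 30 was as large, so the 2 measures differ on this. Among the 12 that part all same-numbered MOLM-13 pairs the highest other r was 0.227. A trend with abundance and transcript length is argued against as the whole cause, since r was 0.244 after its removal, and so are the fixed myeloid lists alone, since r was 0.243 without their 62 genes. A shared response to the inhibitor remains a hypothesis beside chance.

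Of the 5 genes called over both lines, 4 were small RNA genes, which made up 4.54% of the tested genes in MOLM-13 and 2.41% in ER-Hoxa9. The residual SD of small RNA genes was 3.94 times that of other genes of like mean in MOLM-13 and 6.15 times in ER-Hoxa9, which is consistent with unstable values of genes shorter than a sequenced fragment. For a change of the host transcript of MIR191 the outcome depends on the fit. DALRD3, which spans MIR191 (GRCh38 chromosome 3, 49015488 to 49022293), had a fold change of -0.22 ± 0.17 (0.08 with the replicate block). Its fall was close to its SE without the block and well beyond it with the block, so a change of the host is not excluded. DALRD3 kept most of its level, at 18.2 ± 1.69 and 15.5 ± 1.73 TPM, while MIR191 was listed at 0. A specific loss of the microRNA gene stays open, untested.

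MOLM-13 libraries grouped by replicate number, with the lowest same-number correlation of deviations at 0.44. It was 0.41 after MIR6723 and MIR4461 were removed, which argues against their share as the cause. The Spearman correlation across genes of transcript length with the deviation of the replicate 3 libraries was -0.20 in DMSO and -0.25 in WM-1119, too weak to decide, so a length bias cannot be told apart from other shared conditions. With 10 splits of the 6 libraries no share under 0.05 can be reached: 6 splits called as many genes as the real one, itself included, which called 1 against 6 in the highest other, and 8 called as many lists, itself included, 10 against 18. The split that sets DMSO 1 with WM-1119 1 and 2 gave 3031 genes at an unadjusted p under 0.05 against 379, which points to a structure of the samples, while with the replicate block the real split gave 2256 against 357 in the highest other that parts all pairs. By lists the blocked real split showed no such excess, with 14 called against 14 in the highest of those others.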
